A study of Mus musculus with 34 samples.

How the data were processed

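Total RNA from 2 C57BL/6 mouse embryonic stem (ES) cell lines, C2 and D4, both derived from blastocysts, was measured on 2 Affymetrix array types, MOE430A and MOE430B. ES cells are pluripotent cells that can contribute to a chimeric mouse when placed in an embryo, and to its germ line. Each line was sampled in 3 states, which the labels name late passage attached, late passage detached and early passage. There were 3 RNAs per line and state, except 2 for detached D4, giving 17 RNAs and 34 arrays.

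Per the labels, late-passage cells gave high chimerism and germline transmission, and early-passage cells gave low chimerism and none. Late-passage cells grew in a medium labelled Thromb-XTX-WES and early-passage cells in DMEM with 15% fetal bovine serum, both with LIF, at 5% CO2 and 37 C. Passage, medium and chimerism therefore changed together. The cells grew on mouse embryonic fibroblast feeders, which the labels name as the contaminating cell type, at an estimated purity of about 90%. Per the labels' protocols, cells were trypsinized lightly so that feeders stayed behind, and the suspension was replated for 1 hour. The labels do not say to which surface attached and detached refer. They also do not say whether the RNAs of a group came from separate cultures, so p-values measure the spread between these RNAs, which may be technical.

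The deposited values are signal intensities per probe set, made with MAS5 per the submitters' processing notes. MAS5 combines perfect-match and mismatch probes into 1 linear value and scales each array separately. The 2% trimmed mean of the deposited intensities was 1500 to 1501 on every array. The MAS5 version and detection calls were not given in the sources used here. Per the file headers of the scanner information, the MOE430B arrays came from 2 chip lots, of which the second held only early-passage RNAs (C2 replicate 2 and all 3 of D4). Fluidics runs were inferred from the station and times logged in those headers. Arrays of a station logged close together on a day were taken as 1 run.

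The deposited intensities were analysed as log2(signal + 16), with no further scaling, so fold changes of dim probe sets are understated. A probe set was tested if it exceeded its array's median on at least 2 of the 17 arrays of its type. Control probe sets were left out. This left 14160 probe sets on MOE430A and 16213 on MOE430B. Of 22690 probe sets on MOE430A, 20393 had 1 gene symbol, 691 several and 1606 none. Of 22575 on MOE430B, the numbers were 14674, 245 and 7656. Symbols came from the platform annotation and were updated by gene identifier from the reference gene table for GRCm38.p6, which matched 20364 and 14499 probe sets. That table also gave chromosomes and gene order. No coordinates are printed, because no build was used to make the values.

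Each array type was fitted separately with limma 3.58.1 in R 4.3.3, with 1 coefficient per line and state and a spread shared by all 6 groups. The main contrast was late minus early passage, with late as the equal mean of attached and detached, averaged over both lines. The other contrasts were detached minus attached, D4 minus C2, each change within a line, and the difference between lines in each change. P-values were adjusted by the Benjamini-Hochberg method within each array type. A probe set was called at an adjusted p under 0.05, and calls on both array types were added up. Contrasts written here as late minus early are positive where late passage was higher.

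Before the data were examined, 26 gene lists were fixed. They cover naive pluripotency, general pluripotency, primed epiblast, extraembryonic endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, feeder fibroblast, imprinted, sex chromosome, 2-cell-like and germ line genes. The others cover the p53 response, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, the amino acid and ER stress response, the oxidative stress and metal response, the immediate early and serum response, the FGF and ERK response, the BMP and TGF-beta response, the Wnt response, adhesion and junctions, interferon and antigen presentation, the cell cycle, and DNA methylation and chromatin. Each gene was represented by its brightest tested probe set, on MOE430A where it had one, giving 14105 genes. Lists were tested on MOE430A with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation. The same test was applied to the genes of each chromosome.

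The rule for named genes, also fixed before, took the 6 highest and 6 lowest called changes with the same sign in both lines and a mean log2 signal above 8 in the brighter group. For the line differences it took up to 3 in each direction. It added up to 4 called members per list and a fixed set of pluripotency, lineage, imprinted and fibroblast genes. Any other gene named was chosen after its values were seen.

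RNA quality was read from the ratio of 3' to 5' control probe sets. On simulated data for the late minus early contrast with 200 changed probe sets per array type, limma called 74.6%, 97% and 100% of those changed by log2 1, 2 and 3 on MOE430A, and 25.4%, 73.1% and 87.9% on MOE430B. It called 4 unchanged probe sets on each. Precision was limited by the number of arrays.

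The alternatives were pseudocounts of 1 and 64, no filter, a 75th percentile filter, quantile normalization, median centring, the replicate number as a block, and fluidics run as a random block. A minimum log2 change of 1, late attached or detached alone against early, the feeder list as a covariate, 1 mean per line and state, other probe sets of a gene and leaving out each RNA in turn were tried too. After the data were examined, array weights, a fixed run block within C2 and leaving out 2 doubted RNAs were added.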

Results

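Expression was measured in 2 mouse ES cell lines, C2 and D4, whose early-passage cells gave low chimerism and no germline transmission and whose late-passage cells gave high chimerism and germline transmission. The labels name 2 kinds of late-passage cells in each line, attached and detached. Of 17 RNAs, 3 came from each line and state, except for detached D4 with 2, and each RNA was hybridised to both array types. The median signal per array was 529 to 817 on MOE430A and 763 to 989 on MOE430B. Replicates within a group correlated at r = 0.866 to 0.957 across genes on MOE430A and 0.684 to 0.818 on MOE430B, so MOE430B had less power. RNAs of different groups correlated almost as well, at r = 0.823 to 0.956 and 0.659 to 0.818.

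The arrays of 2 RNAs stood apart. For attached C2 replicate 1, the 5th percentile of signal was 109 on MOE430A, against at most 37.6 on the other arrays. For attached D4 replicate 3, the 3' to 5' ratio of Actb, a sign of RNA quality, was 1.84 on MOE430A, against at most 1.21 elsewhere. Its MOE430A array was also the only array without the logged protocol of the others. Transcripts on the feeder fibroblast list also differed between states. No RNA of feeders alone was measured, so the cells that these transcripts came from were not tested. The mean log2 signal of the feeder list in C2 was 11.57 ± 0.36 (SD, n = 3) in early passage, 11.1 ± 0.17 (n = 3) in late attached and 9.64 ± 0.42 (n = 3) in late detached cells. In D4 it was 11.86 ± 0.29 (n = 3), 10.76 ± 0.43 (n = 3) and 9.37 ± 0.30 (n = 2).

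**Figure D1:**
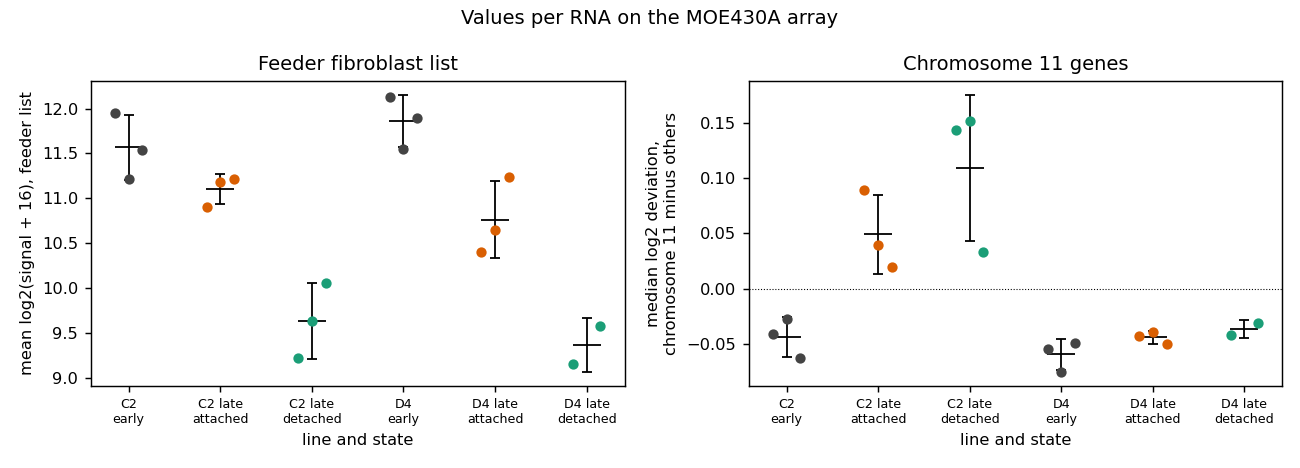
Each dot is 1 RNA on the MOE430A array, grouped by line and state, and bars give the mean ± SD. The left panel shows the mean log2(signal + 16) of the feeder fibroblast list, lowest in the detached cells of both lines, and the right panel shows the median log2 deviation of chromosome 11 genes from the other chromosomes, which lay between 0.02 and 0.151 in late-passage C2 and below 0 in every other RNA.

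The first comparison asked which genes differed between late-passage cells, which entered the germ line, and early-passage cells, which did not. Late-passage cells of both lines had more transcripts of Srgn, a proteoglycan of secretory granules, and of Cubn, an endocytic receptor of visceral endoderm. They also had more Lefty2, a Nodal antagonist, and Trh, which encodes thyrotropin-releasing hormone. Early-passage cells had more transcripts of the collagen gene Col1a1, of Tagln and Cnn1, which encode proteins of smooth muscle, and of the simple-epithelial keratins Krt8 and Krt18. The core pluripotency factors Pou5f1 and Nanog did not pass the test.

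Srgn was 3.35 log2 units higher in late passage (SE 0.335, limma adjusted p = 0.000235, n = 11 late and 6 early RNAs). The rise was 2.83 for Cubn (SE 0.312, adjusted p = 0.000543) and 1.95 for Trh (SE 0.233, adjusted p = 0.000593). Lefty2 rose by 2.37 on MOE430B (SE 0.259, adjusted p = 0.00481). On that array type all 3 early D4 RNAs and early C2 replicate 2 were on another chip lot than the late RNAs, so that lot and passage cannot be told apart in D4. The early C2 RNAs on the same lot as the late ones had Lefty2 at 9.87 and 10.96, and the lowest late C2 RNA was at 12.19. For these 4 genes, each of the 11 late RNAs lay above every early RNA. Mean log2 signal of Srgn went from 8.34 ± 0.75 in early C2 to 11.13 ± 0.27 in attached and 10.32 ± 0.07 in detached cells, and from 6.55 ± 1.40 in early D4 to 10.98 ± 0.53 and 10.74 ± 0.21. Gbx2, a homeobox gene, rose by 1.85 (adjusted p = 0.0167), and Pla2g7, a phospholipase, by 1.72 (adjusted p = 0.0232). With attached cells alone against early passage, Srgn, Cubn, Lefty2 and Trh still passed the test, at 3.61, 2.80, 2.34 and 1.83, while Gbx2 at 1.24 and Pla2g7 at 1.34 did not. On both array types the attached and early D4 RNAs lay in separate fluidics runs on separate days. In D4 this comparison, here and below, therefore also follows run and day. Pla2g7 also lost its call in 3 of 15 fits without single RNAs.

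Col1a1, a chain of type I collagen, had the largest fall, at -4.21 log2 units (SE 0.410, adjusted p = 0.000214). Next came Tagln at -3.65 (SE 0.410, adjusted p = 0.000554), Acta1 at -3.44 (SE 0.662, adjusted p = 0.012), Cnn1 at -3.08, Ccdc80 at -2.92 and Acta2 at -2.86. Tagln, Cnn1 and the actins Acta1 and Acta2 belong to the contractile apparatus of muscle. With attached cells alone against early passage, Col1a1 at -2.62, Tagln at -2.55, Cnn1 at -2.47 and Acta2 at -2.12 kept their calls, while Acta1 at -3.08 (adjusted p = 0.127) and Ccdc80 at -1.73 (0.23) lost theirs. Except for Ccdc80, these genes were lower in all 11 late RNAs than in every early RNA. The feeder list was lower in the same cells. A dimmer probe set of Acta2 on MOE430B gave 0.08. Another probe set of Col1a1 on MOE430A gave -2.15 (limma adjusted p = 0.00302), by which its fall would not be the largest.

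**Figure D2:**
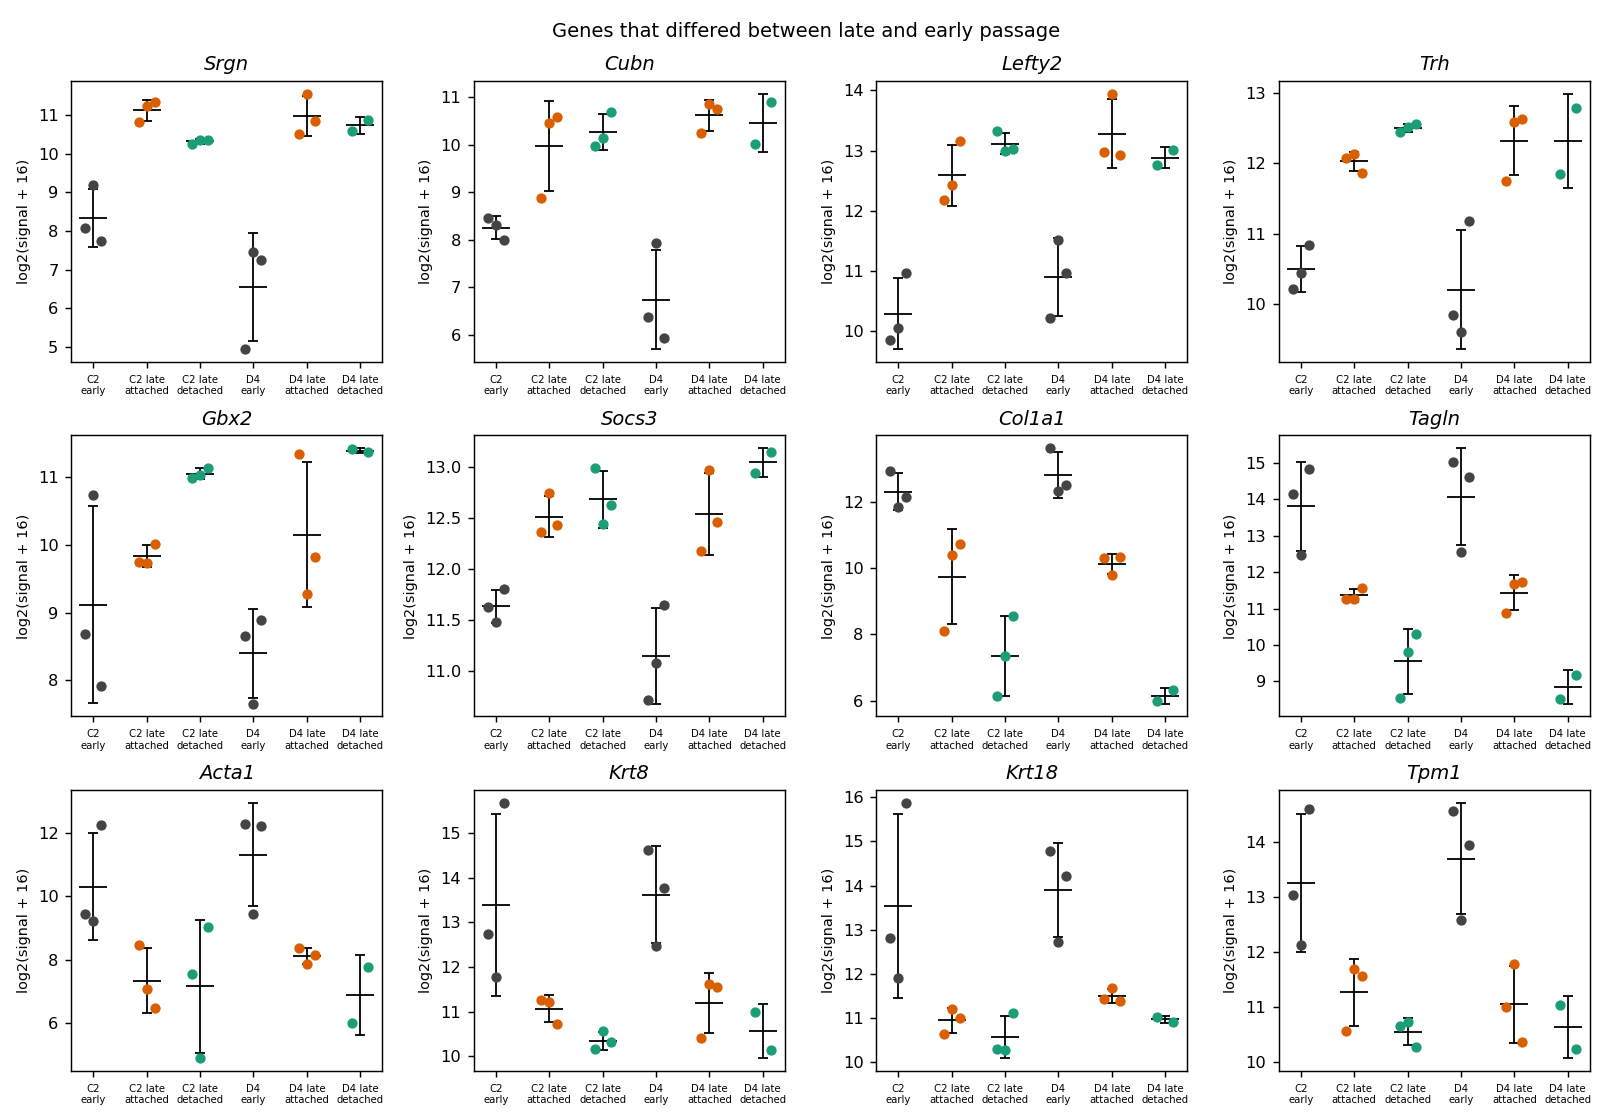
Each dot is the log2(signal + 16) of 1 RNA, grouped by line and state, and bars give the mean ± SD. Srgn, Cubn, Lefty2, Trh and Socs3 lay higher in all 11 late RNAs than in any early RNA, and Col1a1, Tagln, Acta1, Krt8, Krt18 and Tpm1 lay lower, with a wide spread of the keratins in early passage.

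In all, limma called 482 probe sets, 136 higher and 346 lower in late passage, and 226 of them changed at least 2-fold, 30 up and 196 down. MOE430A held 478 of the calls, and 477 of those 478 had the same sign in both lines. A call on the mean of both lines favours a shared sign. Over all 14160 tested probe sets there, 8130 had the same sign in both lines. Array weights gave 752 calls, 288 up and 464 down. The split of higher and lower calls varied, with 45 up and 203 down without a filter, 267 and 383 with the 75th percentile filter, 44 and 150 without D4 early 1, and 234 and 389 without C2 early 2. Leaving out D4 early 1 gave 194 calls in all, C2 early 1 gave 288, C2 early 3 gave 272, D4 detached 1 gave 282 and D4 detached 3 gave 272. Detached cells alone against early passage gave 677 calls, 193 up and 484 down, and attached cells alone 28, 11 up and 17 down. A fit with the feeder list as a covariate gave 0, with 732 probe sets on MOE430A and 747 on MOE430B at an unadjusted p under 0.05. The median SE on MOE430A went from 0.176 to 0.477, so the lost calls do not tell feeder RNA from lower precision. Cubn was then at 3.46 and Col1a1 at -1.46.

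Among naive pluripotency genes, which mark the ground state of mouse ES cells, 4 of 23 rose and none fell, with a median change of 0.39. Adjusted over the list alone, 8 rose and 1 fell. Gbx2 rose by 1.85 and Socs3, a target and feedback inhibitor of LIF signalling, by 1.30 (SE 0.161, adjusted p = 0.000688). Sox2 rose by 0.71 (adjusted p = 0.0269) and Klf5 by 0.55 (adjusted p = 0.032), although 2 other probe sets of Klf5 gave 0.06 and -0.17. Klf5 lost its call in 8 of 17 fits without single RNAs. With attached cells alone, only Socs3 of the 4 kept its call, at 1.13, and Sox2 was at 0.49 and Klf5 at 0.53. The feeder list fell in the same cells. Sox2 lost its call without C2 early 3 (adjusted p = 0.0814), D4 detached 3 (0.0686) or D4 early 1 (0.0872). The list passed camera (adjusted p = 1.95e-05) but not with an estimated correlation (adjusted p = 0.204 with an estimated correlation). Nanog at -0.20 (adjusted p = 0.65), Esrrb at 0.41 (0.0737), Zfp42 at 0.44 (0.294), Klf4 at 0.35 (0.312) and Dppa3 at -0.14 (0.794) were not called.

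Of 21 general pluripotency genes, Lefty2 alone was called, at 2.37, and 4 rose adjusted over the list alone (median 0.25, camera adjusted p = 0.00236; adjusted p = 0.332 with an estimated correlation). Pou5f1, which encodes OCT4, was at 0.29 (adjusted p = 0.315). Of 23 extraembryonic endoderm genes, 5 rose: Srgn by 3.35, Cubn by 2.83, Dab2 by 1.16, Lama1 by 1.11 and Amn by 0.75. Dab2 at 1.32 and Lama1 at 0.94 kept their calls with attached cells alone. Another probe set of Dab2 gave 0.10 (adjusted p = 0.843). Cubn, Dab2 and Amn encode proteins of one endocytic receptor system, and Lama1 a basement-membrane laminin. The median was 0.19, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00239; adjusted p = 0.204 with an estimated correlation). The endoderm transcription factors Gata4 at 0.42 (adjusted p = 0.18) and Gata6 at 0.51 (adjusted p = 0.158) were not called, although another probe set of Gata6 passed, at 1.09, and one on MOE430B gave -0.36.

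Of 27 feeder fibroblast genes, 18 fell in late passage and 24 fell adjusted over the list alone, with a median of -1.50 (camera adjusted p = 1.7e-27; adjusted p = 0.0229 with an estimated correlation). They included Col1a1, Tagln, Acta2, Tnc at -2.18 and Thy1, a fibroblast surface antigen, at -1.40 (SE 0.219, adjusted p = 0.00393). Of 23 immediate early and serum response genes, 11 fell, and 2 rose and 15 fell adjusted over the list alone (median -0.89, camera adjusted p = 2.47e-11; adjusted p = 0.0229 with an estimated correlation). They included Acta1, Cnn1, the myosin light chain gene Myl9 at -2.81, the tropomyosin gene Tpm1 at -2.61 and the thrombospondin gene Thbs1 at -2.60. The immediate early genes Fos at -0.89 (limma adjusted p = 0.084) and Egr1 at -0.32 (0.388) were not called. With attached cells alone against early passage, 3 feeder and 2 serum response genes were called. There Tpm1 was at -2.32 and kept its call, while Myl9 at -1.72, Tnc at -0.69 and Thy1 at -0.60 lost theirs.

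Of 21 p53 response genes, 6 fell and 7 fell adjusted over the list alone (median -0.25, camera adjusted p = 1.62e-05; adjusted p = 0.0183 with an estimated correlation). Plk2, a stress-induced kinase, fell by 1.73 (SE 0.158, adjusted p = 0.000188), Perp by 0.98, Phlda3 by 0.74, Mdm2 by 0.72 and Cdkn1a, which encodes the cell cycle inhibitor p21, by 0.67 (SE 0.154, adjusted p = 0.0289). The feeder list fell alongside. With its mean as a covariate Plk2 was at -1.21 (SE 0.424), Mdm2 at -0.835, Perp at -0.62, Phlda3 at -0.275 and Cdkn1a at 0.08 (SE 0.377), none called. Another probe set of Mdm2 gave 0.13, and one of Plk2 on MOE430B gave -0.40 and was not called. Without single RNAs, Cdkn1a lost its call in 5 of 17 fits, Mdm2 in 9 and Perp in 2. Only Plk2 of these 5 kept its call with attached cells alone, at -1.31, and Perp was at -0.74, Phlda3 at -0.56, Mdm2 at -0.70 and Cdkn1a at -0.36.

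Of 26 adhesion genes, 6 fell and 11 fell adjusted over the list alone (median -0.38, camera adjusted p = 0.000108; adjusted p = 0.204 with an estimated correlation). They included Lgals1 at -1.49, Itga3 at -1.14, Itgb1 at -1.13 and Lgals3 at -1.19, which lost its call in 13 of 17 fits without single RNAs. None of these 4 was called with attached cells alone, at -1.14, -1.06, -0.89 and -0.93. The feeder list fell alongside, and with it as a covariate they were at -0.46, -0.48, -0.58 and -0.64, not called. Of 12 trophoblast genes, only Krt18 at -2.73 (SE 0.467, adjusted p = 0.00664) and Krt8 at -2.72 (SE 0.479, adjusted p = 0.00762) fell, and 5 fell adjusted over the list alone (median -0.36, camera adjusted p = 0.00191; adjusted p = 0.213 with an estimated correlation). Krt8 was at 13.39 ± 2.04 in early C2 and 13.62 ± 1.08 in early D4, and at 10.34 to 11.19 in the means of the 4 late groups. Krt8 at -2.38 (adjusted p = 0.112) and Krt18 at -2.50 (0.0848) lost their calls with attached cells alone. Krt18 was also the only called gene among 12 primed epiblast genes, of which 4 fell adjusted over the list alone (median -0.44, camera adjusted p = 0.0324; adjusted p = 0.22 with an estimated correlation).

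**Figure D3:**
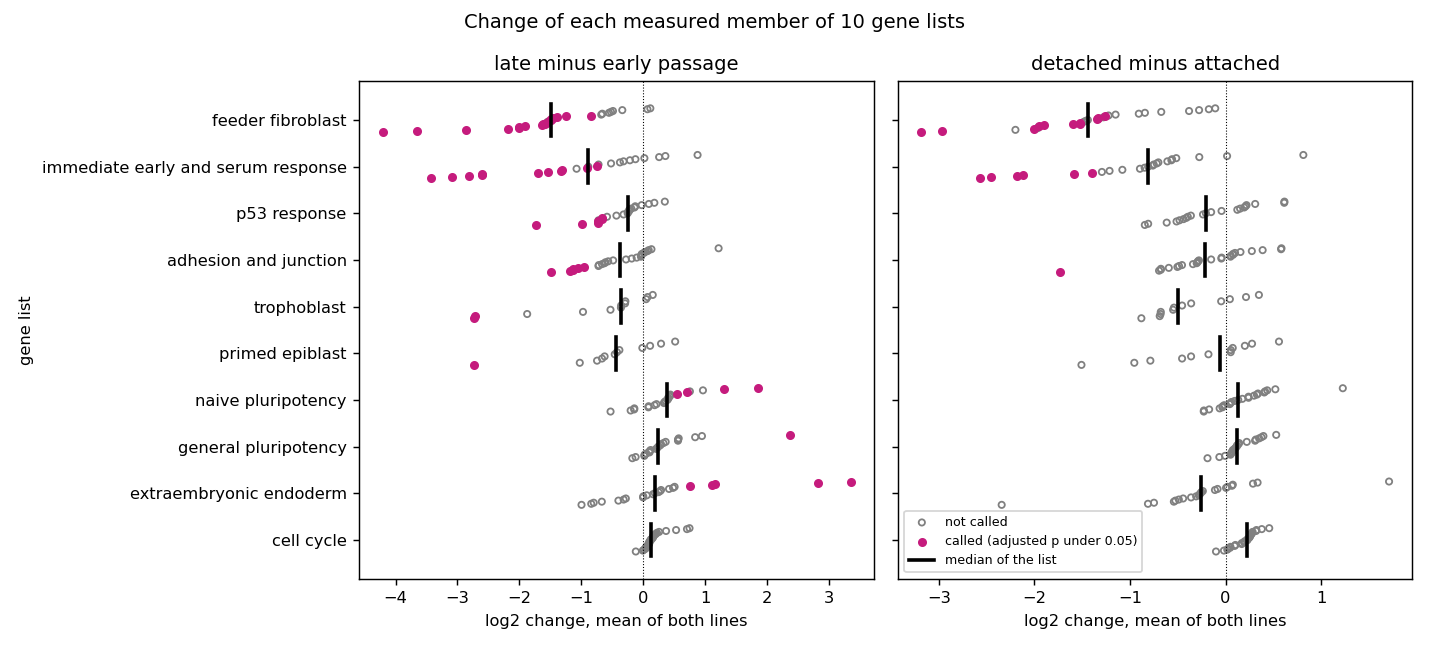
Each circle is the log2 change of 1 measured member of a gene list, averaged over both lines, for late minus early passage and for detached minus attached; filled circles were called and black bars give the list median. Feeder fibroblast and serum response genes lay mostly below 0 in both comparisons, while naive pluripotency genes had medians of 0.39 and 0.13.

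Of 26 imprinted genes, Igf2 fell by 1.41 (SE 0.356, adjusted p = 0.0454), Sgce by 0.84 and Igf2r by 0.69. Adjusted over the list alone, 1 rose and 5 fell (median -0.18, camera adjusted p = 0.0324; adjusted p = 0.204 with an estimated correlation). Igf2 lost its call in 12 of 17 fits without single RNAs, and another probe set of Sgce gave 0.39. Igf2r lost its call in 5 of 17, and another of its probe sets gave -0.11 (adjusted p = 0.792). None of the 3 kept its call with attached cells alone, with Igf2 at -1.29, Sgce at -0.66 and Igf2r at -0.65. Meg3 at 0.16, Peg3 at 0.18 and Mest at -0.01 were not called. Of 16 BMP and TGF-beta response genes, Id2 at -1.85 and Tgfb1i1 at -1.73 fell, the latter with 4 lost calls in 17 fits without single RNAs, and 1 rose and 4 fell adjusted over the list alone (median -0.21, camera adjusted p = 0.0276; adjusted p = 0.229 with an estimated correlation). Attached cells alone gave Id2 at -1.40 and Tgfb1i1 at -0.87, not called. The feeder list fell alongside, and with it as a covariate Id2 was at -1.59 (SE 0.979) and Tgfb1i1 at 0.65 (SE 0.796). Of 19 oxidative stress genes, Txnip rose by 0.82, also the only call adjusted over the list alone (median 0.23, camera adjusted p = 0.033; adjusted p = 0.204 with an estimated correlation). Attached cells alone gave Txnip at 0.22 (adjusted p = 0.732), another of its probe sets gave 0.61 (0.098), and 2 of 17 fits without single RNAs lost its call. None of 26 cell cycle genes was called by limma, and 2 rose adjusted over the list alone (median 0.12, camera adjusted p = 0.00209; adjusted p = 0.224 with an estimated correlation).

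The remaining lists did not pass camera. DNA methylation and chromatin genes had a median of 0.09, with Dnmt3b at 0.11 and Dnmt3l at -0.16. The medians were 0.08 for fatty acid synthesis, 0.03 for cholesterol synthesis, -0.11 for hypoxia and glycolysis, -0.03 for the amino acid and ER stress response, 0.10 for the FGF and ERK response, -0.18 for the Wnt response and 0.08 for germ line genes. They were -0.20 for mesoderm, -0.19 for neuroectoderm, and -0.001 for interferon and antigen presentation, where B2m fell by 1.08. Single calls in these lists included Pdk1, a glycolytic switch kinase, at 0.80, Vegfa at -0.88, Slc7a3 at 0.59, Etv4 at 1.11, Fosl1 at -1.59, Ier3 at -0.74, Ccnd1 at -0.49, Cd44 at -1.05 and Stra8, a gene of meiotic entry, at -1.98 (SE 0.326, adjusted p = 0.00542). Without single RNAs, Vegfa lost its call in 14 of 17 fits, Pdk1 in 12, Ccnd1 in 11, Slc7a3 and Ier3 in 8, Cd44 in 5 and Fosl1 in 1. With attached cells alone none of these genes, Etv4, B2m or Stra8 was called, and Cd44 was at -0.19, Ier3 at -0.29 and Fosl1 at -0.64. The feeder list fell in the same cells. With it as a covariate, Vegfa, Fosl1, Ier3, Ccnd1 and Cd44 turned above 0. Pdk1, Slc7a3, Etv4, B2m and Stra8 kept their signs, and none of these genes was called. Adjusted over the list alone, FGF and ERK genes had 2 up and 4 down. The 4 measured 2-cell-like genes had a median of -0.41 with no call, and the sex chromosome list had 1 measured gene, Xist, at 0.04 (adjusted p = 0.908).

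Within C2, 11 probe sets were called between late and early passage. A dimmer probe set of Cubn, at 3.54, and Lefty2, at 2.56, were among the 6 that rose, and Plk2, Col1a1 and Ccn2, a matricellular growth factor, among the 5 that fell. Within D4, 161 were called, 48 higher and 113 lower. This balance was not stable, with 114 up and 110 down without D4 early 3 and 166 up and 209 down with the 75th percentile filter. Srgn was at 2.39 in C2 (adjusted p = 0.0689) and 4.32 in D4 (0.00309), and the brighter probe set of Cubn at 1.87 (0.113) and 3.80 (0.00309). The count of D4 was 6 without D4 early 1, 38 without D4 detached 1, 67 without D4 attached 1, 72 without D4 detached 3, and 97, 100 and 101 without C2 detached 2, C2 attached 2 and C2 attached 3. That of C2 ranged from 4 without C2 detached 2 to 52 without C2 early 2 or without D4 early 2, and it was 45 without D4 early 1. With the replicate number as a block C2 had 18 calls, and with the fluidics run as a fixed block it had 2. Array weights gave 180 in C2 and 286 in D4. The lines' changes correlated at r = 0.386 across genes on MOE430A, where simulated arrays with no effect gave 0.004; genes are not independent replicates.

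In 4 lists the change within C2 passed with an estimated correlation as well. The feeder list had a median of -1.10 in C2 (adjusted p = 0.0412 with an estimated correlation) and -1.69 in D4 (0.0555). The p53 list had -0.30 in C2 (0.0384) and -0.63 in D4 (0.0555), and the serum response list had -0.76 (0.0384) and -0.98 (0.0717). Primed epiblast genes had a median of -0.66 in C2 (camera adjusted p = 0.00017; adjusted p = 0.0489 with an estimated correlation) and -0.15 in D4 (camera adjusted p = 0.901). Within 1 fluidics run, detached minus early RNAs had medians of -0.73 in C2 and -0.19 in D4 for that list, 0.39 and 0.35 for naive pluripotency, and -1.71 and -2.50 for the feeder list.

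The difference between the lines in the late minus early change was called for 1 probe set, Scnn1a, a subunit of the epithelial sodium channel. It rose by 2.18 in C2 (limma adjusted p = 0.00463) and stood at -1.06 in D4 (adjusted p = 0.0609). The difference, D4 minus C2, was -3.24 (SE 0.351, adjusted p = 0.00317). Its mean log2 signal in C2 went from 7.45 ± 0.28 in early passage to 9.82 ± 0.22 in attached and 9.43 ± 0.04 in detached cells, and in D4 from 9.52 ± 0.35 to 8.45 ± 0.51 and 8.46 ± 0.58. The count was 3 without D4 attached 2 and 2 without D4 early 3.

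The second comparison set detached against attached late-passage cells of each line. Detached cells had fewer transcripts of the matrix genes Col1a1 and Tnc and of Fos and Egr1, immediate early transcription factors, and more of Txnip, an inhibitor of thioredoxin. Col1a1 fell, at -3.19 log2 units (SE 0.493, limma adjusted p = 0.0109, n = 5 detached and 6 attached RNAs), and so did Tnc, which encodes tenascin C, at -2.97 (adjusted p = 0.00302). The feeder list was lower in detached cells of both lines.

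Fos fell, at -2.46 (SE 0.316, adjusted p = 0.00311), as did Egr1 at -1.59 (SE 0.223, adjusted p = 0.00511) and Ccn2 at -2.12 (SE 0.196, adjusted p = 0.000437). Thbs1 at -2.57 (adjusted p = 0.00393), Myl9 at -2.18 (adjusted p = 0.0256) and Mgp, a matrix protein, at -2.89 (adjusted p = 0.026) fell too. Fos and Egr1 are induced within minutes by serum and growth factors. Neat1, a long noncoding RNA of nuclear paraspeckles, rose by 2.18 (SE 0.424, adjusted p = 0.036) on a dim MOE430A probe set, but a brighter one on MOE430B gave 0.48 (adjusted p = 0.855). G6pc3 rose by 1.48, Tnk1 by 1.25, Txnip by 1.21 (SE 0.211, adjusted p = 0.0188) and Ube2g2 by 1.20. Of the genes higher in detached cells, Txnip lost its call in 5 of 17 fits without single RNAs, Neat1 in 11, Tnk1 in 12, G6pc3 in 13 and Ube2g2 in 14. Other probe sets of Tnk1 gave -0.32 and 0.32. Of the genes that fell, Col1a1 lost its call without D4 detached 1 (adjusted p = 0.0716), Mgp in 5 of 17 fits and Myl9 in 6, and another probe set of Col1a1 gave -0.95 (adjusted p = 0.277).

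**Figure D4:**
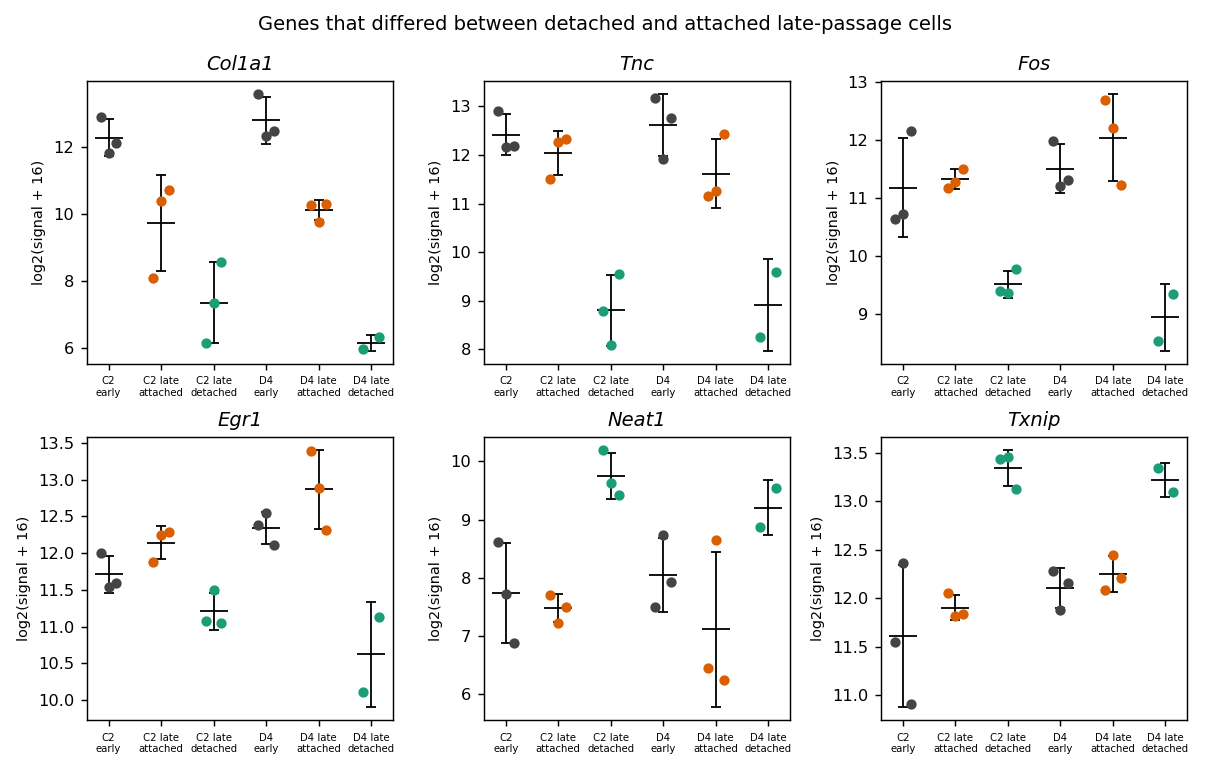
Each dot is the log2(signal + 16) of 1 RNA, grouped by line and state, and bars give the mean ± SD. Col1a1, Tnc, Fos and Egr1 were lower in detached than in attached cells of both lines, and the MOE430A probe sets of Neat1 and Txnip were higher.

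Limma called 66 probe sets, all on MOE430A, 6 higher and 60 lower in detached cells. The count was 35 without C2 attached 2, 32 without D4 attached 2, 39 without D4 attached 3, 22 without D4 detached 1 and 165 without D4 attached 1. After each array was centred on its median, 7 rose and 28 fell, and without the 2 doubted RNAs there were 35 calls. Array weights gave 418, 93 up and 325 down, and 593 within C2. Within C2, 31 were called, 2 up and 29 down, and 6 with the replicate number as a block. That count was 1 without C2 attached 2, 2 without C2 detached 1 and 4 without C2 detached 2. Within D4, 5 were called, all lower. Without D4 attached 2 limma called 0, with 517 probe sets on MOE430A and 928 on MOE430B at an unadjusted p under 0.05. On both array types the attached and detached D4 RNAs lay in separate fluidics runs on separate days. On MOE430A run and state of D4 cannot be told apart.

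Of 27 feeder genes, 11 fell in detached cells and 21 fell adjusted over the list alone (median -1.44, camera adjusted p = 3.39e-22; adjusted p = 0.0553 with an estimated correlation), including Postn at -2.01, Cdh11 at -1.96 and Thy1 at -1.60. Postn lost its call in 5 of 17 fits without single RNAs and Cdh11 in 1. Of 23 serum response genes, 6 fell and 15 fell adjusted over the list alone (median -0.81, camera adjusted p = 3.85e-13; adjusted p = 0.0409 with an estimated correlation). Cell cycle genes had a median of 0.23 with no call by limma, and 24 of 26 were above 0 (camera adjusted p = 1.8e-05; adjusted p = 0.221 with an estimated correlation). Naive pluripotency genes had a median of 0.13 (camera adjusted p = 0.0404; adjusted p = 0.527 with an estimated correlation), and none was called. General pluripotency (median 0.12), DNA methylation (0.16), BMP and TGF-beta (-0.45), hypoxia (-0.22), Wnt (-0.24), mesoderm (-0.32) and extraembryonic endoderm genes (-0.26) passed camera too, but none with an estimated correlation. Cd44, a hyaluronan receptor on the Wnt and adhesion lists, fell, at -1.73, and so did Fosl1, on the FGF and ERK list, at -1.91, with 1 and 15 lost calls in 17 fits.

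Several genes called in late passage were not called between attached and detached cells. Srgn was at -0.53, Cubn at 0.07, Lefty2 at 0.07, Trh at 0.24, Krt8 at -0.68, Krt18 at -0.46, Acta1 at -0.70 and Tpm1 at -0.57. On MOE430A, 45 of the 60 probe sets lower in detached cells were also called lower in late passage, where independent lists would share 1.46. The changes in both comparisons correlated at r = 0.425 across genes, with a covariance of 0.0707. Simulated arrays with no effect, in which both comparisons used the late RNAs in the same way, gave 0.061 and 0.0044. The simulation drew every probe set and RNA independently. It therefore does not cover deviations of a late RNA that many genes share, which would enter both comparisons.

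The third comparison set D4 against C2 over the 3 states. Limma called no probe set; 867 on MOE430A and 1122 on MOE430B had an unadjusted p under 0.05, and no gene list passed camera. Pou5f1 differed by -0.02, Sox2 by 0.36, Nanog by 0.44 and Col1a1 by -0.10, all with adjusted p of at least 0.795. Without D4 attached 1 the count was 1, and without D4 detached 3 it was 2. The interaction of line and attachment was called for 3 probe sets on MOE430B, from 4930434J06Rik, 4930556A17Rik and Zfp980. The attached and detached D4 RNAs lay in separate runs on separate days on that array type too.

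Chromosome 11 was the only chromosome whose genes passed camera. In C2, the 762 measured genes of chromosome 11 were shifted by 0.13 on the log2 scale in late against early passage relative to the other chromosomes (camera adjusted p = 0.00151; adjusted p = 0.018 with an estimated correlation). In D4 minus C2 the shift was -0.09 (camera adjusted p = 1.89e-05, and 0.00333 with an estimated correlation). That contrast averages all 3 states, so it includes the same late C2 RNAs. The mean deviation per RNA on MOE430A was -0.044 in early C2 and -0.059 in early D4. It was 0.079 in late C2 and -0.041 in late D4. On MOE430A the D4 minus C2 contrast also cannot be told apart from fluidics run. On MOE430A all 6 late C2 RNAs lay above the 3 early ones (exact permutation test, two-sided p = 0.0238, adjusted p = 0.357 over the chromosomes in C2). With 84 splits, the adjusted p of 1 shifted chromosome among 20 cannot fall under 0.05, so the adjusted value decides nothing. For chromosome 11 in D4 on MOE430A, 4 of 5 late RNAs lay above every early one (exact permutation test, two-sided p = 0.0357). In D4 on MOE430A, chromosomes 1, 2 and 5 changed by -0.03, 0.027 and 0.042 (exact permutation test, two-sided p = 0.0179 each). On MOE430B all 6 late C2 RNAs lay above every early one for chromosome 4 (exact permutation test, two-sided p = 0.0357). Separation by this test was therefore not particular to chromosome 11 or to C2. The difference between lines in the late minus early shift of chromosome 11 was not called (-0.08, camera adjusted p = 0.461). On MOE430B the shift in C2 was 0.04 (bootstrap interval -0.028 to 0.102), and 2 of the 6 late C2 RNAs lay above every early one. Within 1 fluidics run, detached minus early C2 RNAs had a shift of 0.13.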

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

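The tests of chromosome 11 on single RNAs, on feeder RNA and on a gain of the chromosome were chosen only after the result was seen; the other tests were chosen before it was seen.

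A difference between the lines in the late minus early change was called for Scnn1a, at -3.24 (D4 minus C2), and no fit without a single RNA lost it. Scnn1a fell below the 75th percentile filter, under which the 3 calls were other probe sets. Of 100 splits of the RNAs, 14 gave at least 1 call for this contrast, with 3 as the highest other, so chance was not excluded for the count of 1. The interaction of line and attachment was called on MOE430B for 4930434J06Rik at -4.42, 4930556A17Rik at -4.31 and Zfp980 at 3.44. The first of these lost its call in 12 of 17 fits without single RNAs and the second in 8, and Zfp980 fell below the filter, and was not tested, in 2. Of 100 splits, 4 gave 3 or more calls, with 66 as the highest other, in the split that swapped attached and detached in C2, which follows the structure of the samples.

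Lists differed between lines in the late minus early change by camera. Primed epiblast genes differed by 0.42 (adjusted p = 0.601 with an estimated correlation) and DNA methylation genes by 0.25 (0.699). The feeder list differed by -0.57 (0.781) and interferon genes by -0.58 (0.601).

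The first pattern weighed was the fall of genes in late passage, 346 probe sets. For 58 genes called lower in D4 and not on the feeder list, the mean detached minus attached change in C2 was 0.918 times the mean late minus early change (interval 0.749 to 1.12), against 1.22 (0.936 to 1.68) for the feeder list. The intervals overlap, so a smaller share of feeder RNA as the whole cause cannot be told apart from a change in the ES cells. Within 1 fluidics run, with 2 detached and 2 early RNAs, the median in C2 was -1.07, against -1.32 over all its detached and early RNAs. The interval of -1.57 to -0.705 was taken over genes and does not measure the spread between RNAs. The median argues against the run for these RNAs. Medium, passage and germline capacity, which the labels change together, stay open and were not tested separately.

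The second pattern was the rise of genes in late passage. For 28 genes called higher in D4, the same ratio in C2 was 0.417 (interval 0.14 to 0.924), against 1.22 (0.936 to 1.68) for the feeder list. ES transcripts that rise because feeder RNA is diluted need not share the ratio of feeder transcripts. The comparison therefore cannot decide whether less feeder RNA was the whole cause. Within 1 fluidics run, with 2 detached and 2 early RNAs, the median in C2 was 0.572 (interval over genes 0.233 to 0.867). This argues against the run for these RNAs, but the interval does not measure the spread between RNAs. As a hypothesis, these genes may differ in the ES cells themselves. Less feeder RNA stays open, and medium and passage number were not tested.

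The third pattern was the shift of chromosome 11 in late-passage C2. It does not rest on 1 RNA, as the shift was at least 0.109 and at most 0.142 with any C2 RNA left out. Within 1 run, with 2 detached and 2 early RNAs, the shift was 0.126 (interval over genes 0.084 to 0.16). The detached RNAs of that run were at 0.151 and 0.033 and the early ones at -0.041 and -0.027. This argues against the run for these RNAs, but the interval does not measure the spread between RNAs. Feeder RNA stays open, because D4 had a shift of 0.029 but the difference between lines had an adjusted p of 0.461. A gain of chromosome 11 in part of the cells may be a source: 10 of 10 stretches of the chromosome were above 0 in C2, yet 8 of 10 were in D4 too, and MOE430B had 0.044 (interval -0.028 to 0.102), so this stays open.

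Other splits of the same RNAs were counted for each model. For late minus early, 1 of 100 splits, the real one, gave 482 calls, with 12 as the highest other. This argues against a chance split of these RNAs. It cannot exclude a chance difference between cultures, because the RNAs of a group may come from 1 culture. With 1 mean per line and state the count was 1. For C2 it was 2 of 100, with 11 calls and 12 as the highest other. For D4 it was 2 of 100, with 161 calls and 177 as the highest other. For detached minus attached it was 2 of 100, with 66 calls and 317 as the highest other. The splits with 177 and 317 calls put D4 attached 1 with the 2 detached D4 RNAs, which points to a structure of the samples. For detached minus attached in C2, with 31 calls and 1 as the highest other, the 10 splits are too few for a share under 0.05; only the real one, 1 of 10, gave 31. For D4 minus C2 the real count was 0, which all 100 splits must reach, so this count of splits says nothing; the highest other was 5.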

How the results depend on the processing

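Array weights, the fixed run block in C2 and the fits without 2 doubted RNAs were chosen after the data were examined. Counts are given for late minus early (482), within C2 (11) and within D4 (161), detached minus attached (66), within C2 (31) and within D4 (5), and the line differences (1 and 3). D4 minus C2 had 0 under each alternative except single RNAs left out. The cause of a change was not tested unless stated.

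Without a filter the counts were 248, 6 and 42 for late minus early, 5 for detached in C2 and 0 for detached in D4, where 1032 and 1163 probe sets on the array types had an unadjusted p under 0.05 by limma. With the 75th percentile filter, which tests fewer probe sets, they were 650 for late minus early, 105 in C2 and 375 in D4, 10 for detached in D4, and 3 and 1 for the line differences. A pseudocount of 64 gave 17 in C2. A minimum log2 change of 1 gave 226. Quantile normalization gave 39 for detached, 6 in C2 and 3 in D4, and median centring 35, 4 and 1. Centring also gave 89 in D4 for late minus early, 37 up and 52 down, against 48 and 113 as deposited. It moved the median change of tested MOE430A probe sets to 0.13 in late D4 and to 0.20, 0.27 and 0.13 for detached in both lines, C2 and D4. Array weights gave 752, 180 and 286 for late minus early and 418, 593 and 13 for detached. Without the doubted RNAs the counts were 506 for late minus early, 35, 14 and 3 for detached, and 1 for its line difference.

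Attached cells alone gave 28, 5 and 7, and detached cells alone 677, 120 and 151. With 1 mean per line and state, which leaves few degrees of freedom, the counts were 1 for late and 0 for detached, where 2193 and 1142 had an unadjusted p under 0.05. With the feeder covariate the counts were 0, 0 and 0. The covariate follows the groups, and the median SE on MOE430A went from 0.176 to 0.477. Srgn was then at 2.40 (SE 0.916, before 3.35 with SE 0.335) and Col1a1 at -1.46 (SE 0.846, before -4.21 with SE 0.410). Other changes roughly kept their size or grew, with Cubn at 3.46 (SE 0.871, before 2.83) and Trh at 2.61 (before 1.95). Socs3 was at 1.24 (before 1.30), Ccn2 at -1.72 (before -1.69) and B2m at -1.70 (before -1.08). Of called genes, signs turned for Ccdc80 (0.56), Thy1 (0.28), Cdkn1a (0.079), Tnc (0.13), Vegfa (0.37), Fosl1 (0.17), Ier3 (0.094), Ccnd1 (0.24), Tgfb1i1 (0.65) and Cd44 (0.22). Among called genes, other probe sets turned the sign of Acta2 (0.084), Klf5 (-0.17), Sgce (0.39) and Mdm2 (0.13) in late passage and of Tnk1 (-0.32) in detached cells.

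Same-numbered RNAs did not deviate together: the median correlation of residuals was -0.011 on MOE430A and -0.002 on MOE430B, and 7 of 40 pairs were over 0.1 on MOE430A. The numbers therefore do not pair the samples. With the replicate number as a block the counts were 431, 18 and 147 for late minus early, 63, 6 and 4 for detached, and 1 and 2 for the line differences. The random run block gave 489, 14 and 162, and 72, 32 and 6. The fixed run block gave 2 for late C2 and 13 for detached C2; on MOE430A it could not be fitted for contrasts in D4.

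Leaving out single RNAs gave 194 to 623 for late minus early, 4 to 52 in C2, 6 to 240 in D4, 1 to 3 for their difference, 22 to 165 for detached, 1 to 31 in C2, 0 to 7 in D4, 0 to 3 for their difference and 0 to 2 for D4 minus C2. Over the 83 results on named genes, 2050 values stayed on their side of the threshold, among them values of uncalled genes that turned sign. Of the others, 399 lost the call, 3 gained it and 15, of called genes, turned sign. MOE430B held 4 of the 482 calls, with a median SE of 0.319 for late minus early against 0.176 on MOE430A.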

Other observations

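The tests reported here were chosen after the values were seen, and so were the genes. Values are those of the brightest called probe set, and other probe sets of Ntn1 (0.11), Timp2 (-0.67), Timp3 (-0.87), Csf1 (-0.75) and Ptgs2 (-1.79) were not called in late passage.

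Among genes on no list, late-passage cells had more Ntn1, which encodes the guidance cue netrin-1, Gpx2, a glutathione peroxidase, and Fzd5, a Wnt receptor. Ntn1 rose by 1.64 (limma adjusted p = 0.00528), Gpx2 by 1.55 (0.0217) and Fzd5 by 1.05 (0.049). Socs2, like Socs3 a feedback inhibitor of cytokine signalling, rose by 0.79 (0.0215), and Zfp57, which keeps methylation at imprinted loci, by 0.96 (0.0465). None of the 5 genes was called between attached and detached cells.

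Other genes fell in late passage. They included the metalloproteinase inhibitors Timp2 at -1.71 (adjusted p = 0.000593), Timp3 at -1.84 (0.0075), the cytokine Csf1 at -1.57 (0.00866) and Ptgs2, an inducible prostaglandin synthase, at -1.71 (0.0257). Cdkn2b, a cell cycle inhibitor induced by TGF-beta, fell, at -1.73 (0.0118), and Hmga2, a chromatin protein, did so at -1.29 (0.00237). The feeder list fell in the same cells.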
